A study of Saccharomyces paradoxus and Saccharomyces cerevisiae and Nakaseomyces glabratus with 58 samples.

How the data were processed

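Polyadenylated RNA was sequenced from 6 yeast species: Saccharomyces cerevisiae, Saccharomyces paradoxus, Candida glabrata, Naumovozyma castellii, Kluyveromyces lactis and Schizosaccharomyces pombe. Per the labels, the reads were paired and 25 bases long, the cells grew in a medium abbreviated BMW, log phase meant an optical density of 0.6 to 0.8, and lag phase meant 30 or 60 min after glucose was given back. The labels list 58 samples. One of them, a wild type S. cerevisiae sample at 60 min, has no count column, is the sole sample of its group and was not used here. The other 57 samples form 19 groups of 3 replicates lettered A to C. The N. castellii deletions, delta Scas551.1 and delta Scas719.24 in the labels, are named here by the SFP1 paralog with 5 and 0 counts left in them, NCAS0A02570 and NCAS0J01590. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between samples.

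The deposited count tables hold one estimated count per gene and sample, that is RSEM expected counts, with no normalization by the authors beyond that estimate; between 59.6% and 96.7% of their values were whole numbers within a tolerance of 1e-06. Per the submitters' processing notes, RSEM 1.2.11, Bowtie 1 and edgeR were used, with no role stated for each. The same notes name ASM294v2, the S. pombe assembly, for all samples; the genome builds and annotations of the other species are not given in the sources used here. The deposited log ratio tables per gene are log2 ratios that the authors made from the same libraries. Their base and sign were read from the values: regressed on the fold changes computed here, the 11 columns gave slopes between -1.004 and -0.878 and correlations across genes between -0.99999 and -0.931, so their sign is wild type over altered strain. The deposited log ratio tables per orthogroup also hold 25 microarray columns, in another unit: log ratios by the authors whose base, sign and replication are not stated. The sign of these was turned as for the sequencing columns. The deposited orthology table gives each gene the number of its orthogroup, another kind of value; through it, genes of the other species carry the S. cerevisiae name or names of their orthogroup. The deposited TMM tables, a second orthology table and the S. paradoxus table per orthogroup hold the same information again and were not used here.

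Expected counts were rounded. For each species, all groups entered one edgeR quasi-likelihood fit (glmQLFit and glmQLFTest) with TMM factors, after filterByExpr with default settings. A gene passed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Standard errors are the absolute log2 fold change divided by the square root of the F statistic, and log2 fold changes are altered strain over wild type unless another order is named. CPM values use TMM-scaled library sizes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

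The design compares each mutant with the wild type of its species and phase, which gives 11 comparisons. To these were added 3 comparisons between altered strains of one species, 2 tests of whether the deletion effect in S. paradoxus differed between lag and log phase, and 7 tests of whether a mutant effect differed from that in the S. cerevisiae deletion, on orthogroups with exactly 1 gene in both species. Another 3 comparisons, of 60 with 30 min in S. paradoxus, were chosen after seeing the data. Similarity of comparisons was described by Pearson and Spearman correlations of fold changes across orthogroups, with Fisher's exact test of shared calls over 55 pairs.

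The 29 gene lists were written from S. cerevisiae gene names: cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, translation factors, cytosolic tRNA synthetases, mitochondrial ribosomal proteins, oxidative phosphorylation, TCA and glyoxylate cycles, glycolysis and fermentation, induced environmental stress response, trehalose and glycogen, heat shock chaperones, proteasome, amino acid biosynthesis, sulfur and methionine, purine and pyrimidine synthesis, ergosterol synthesis, G1/S cell cycle, histones, autophagy, peroxisome and fatty acid oxidation, hexose transport, iron regulon, phosphate regulon, cell wall, mating and haploid-specific genes, meiosis and sporulation, auxotrophic marker genes, and TORC1 and ribosomal gene regulators. Lists with at least 5 measured genes were tested with limma camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg over the lists of a comparison. An orthogroup belongs to a list if one of its S. cerevisiae names does, so lists can hold paralogs that do something else: the oxidative phosphorylation list holds the mitochondrial protease gene MAS1 with COR1, and the G1/S list holds isocitrate lyase genes grouped with MCD1. Counts "adjusted over the list alone" use Benjamini-Hochberg over the members of the list.

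Genes are named by a rule: the deleted or tagged gene and its paralog; the 5 largest rises and 5 largest falls among genes past the threshold with a mean log2 CPM of at least 4, every altered library on one side of every wild type library and a S. cerevisiae name; up to 3 members with the largest change in the list's direction for each list that passed; and a panel of RPL3, RPS3, RPP0, NOP1, NSR1, NOP56, RPA190, TEF1, CIT1, HSP104, HSP12 and TPS1. Mating-type genes and strain markers named beyond this were chosen after their values were seen. Groups, comparisons, lists, tests and the rule for named genes were fixed before the data were examined.

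A count of 0 allows up to 3 counts, taken over the group. Shares of single counts carry exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only. The procedure was tested on simulated data: with 200 genes changed in counts drawn at the depth and spread of the libraries, the fits of the comparisons with wild type recovered between 29.7% and 80.6% of 1.5-fold changes, between 60.0% and 98.5% of 2-fold changes and between 86.4% and 100% of 4-fold changes. The lowest shares belonged to S. paradoxus at 30 min. Between 2.16% and 8.23% of the genes called in these simulations were unchanged ones.

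The alternatives tried were RLE factors, library size without TMM, TMM factors without the ribosomal lists, no filter on low counts, only the groups compared, the replicate letter as a block, each library left out in turn, DESeq2, a minimum absolute log2 fold change of 1, an estimated inter-gene correlation, fry, counts summed per orthogroup and, for the similarities, orthogroups outside the ribosomal lists. Alternatives chosen after seeing the data were leaving out ribosomal RNA genes, thinning the S. paradoxus libraries to lag-phase depth and leaving out the S. paradoxus library of lowest depth.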

Results

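The series measured messenger RNA in 6 yeast species in which SFP1, the gene of a zinc finger transcription factor known from S. cerevisiae as an activator of ribosome genes, had been deleted or altered. There were 19 groups of 3 libraries. At log phase they were wild type, deletion and a strain with HA-tagged Sfp1 in S. cerevisiae; wild type and 2 single deletions of the SFP1 paralogs in C. glabrata and in N. castellii; wild type and deletion in S. paradoxus and K. lactis; and wild type and libraries labelled deletion in S. pombe. S. paradoxus wild type and deletion were also sampled 30 and 60 min into lag phase after glucose repletion. Total counts ranged from 1360916 to 3447874 per library in S. cerevisiae, C. glabrata, N. castellii, K. lactis and the S. paradoxus log phase libraries, and from 712972 to 2252092 in S. pombe. The S. paradoxus lag phase libraries held 418292 to 640282 counts, except deletion replicate A at 30 min with 34081. Values after ± are standard errors of log2 fold changes from edgeR, or SD where CPM are given, with n = 3 libraries per group throughout; adjusted p-values of genes are from edgeR with Benjamini-Hochberg, and those of lists from limma camera. Largest or leading changes are those among genes with a mean log2 CPM of at least 4 and every altered library on one side of every wild type library.

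In S. cerevisiae, SFP1 (YLR403W, build R64, chromosome XII, 925568 to 927619, plus strand) had 0 counts in the 3 deletion libraries against 561 in wild type (81.3 ± 6.28 CPM), at least 253-fold lower with a floor of 3 counts over the group. Among 137 cytosolic ribosomal protein genes 126 fell and 5 rose, with a median of -0.82, led by RPS9A (YPL081W, -3.49 ± 0.11) and RPL8A (YHL033C, -2.91 ± 0.06). Of 152 ribosome biogenesis genes 115 fell and 6 rose, among them NSR1 (YGR159C, -1.70 ± 0.07, adjusted p = 4.6e-12), of pre-rRNA processing, and the GTPase gene NOG2 (YNR053C, -1.53 ± 0.09). For both lists the call (adjusted p = 4.5e-32 and 1.1e-18) was lost with an estimated correlation (adjusted p = 0.111 and 0.0753). Ribosomal protein genes made up 10.998 ± 0.343% of counts in the deletion and 15.7 ± 0.120% in wild type.

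Translation factors fell in 35 of 38 cases, as did 20 of 21 cytosolic tRNA synthetase genes (adjusted p = 6.2e-16 and 1.8e-13, and 0.00806 and 0.065 with an estimated correlation); examples were YEF3 (YLR249W, -1.54 ± 0.07), elongation factor 3, and the tryptophan enzyme WRS1 (YOL097C, -1.58 ± 0.07). The phosphate regulon fell in 13 of 14 genes, including SPL2 (YHR136C, -3.60 ± 0.14). Smaller falls were called for amino acid biosynthesis (36 fell, 11 rose of 53), mitochondrial ribosomal proteins (37 fell, 7 rose of 74), purine and pyrimidine synthesis (17 and 5 of 27), RNA polymerases I and III (15 and 3 of 27), and glycolysis and fermentation (12 and 3 of 20). All 5 calls ended with an estimated correlation, at adjusted p = 0.379, 0.111, 0.205, 0.111 and 0.673 in this order. The mating and haploid-specific list fell too (9 and 2 of 20, adjusted p = 0.0302, 0.111 with an estimated correlation). Within that list the a-type receptor gene STE2 (YFL026W, -0.93 ± 0.06) fell while the alpha-type genes STE3 (YKL178C, 3.40 ± 0.49) and SAG1 (YJR004C, 1.21 ± 0.12) rose, the last 2 from 0.864 and 29.4 CPM in wild type.

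Rises were called for peroxisome and fatty acid oxidation (10 of 24 rose), meiosis and sporulation (7 of 14) and the iron regulon (7 of 18, led by the heme oxygenase gene HMX1 (YLR205C, 2.18 ± 0.19)), with adjusted p = 0.111, 0.111 and 0.233 with an estimated correlation. Among the 5 largest rises were the small heat shock gene HSP26 (YBR072W, 3.77 ± 0.15), the glucan synthase gene GSC2 (YGR032W, 3.14 ± 0.08), and ARO10 (YDR380W, 2.89 ± 0.08) of aromatic amino acid breakdown. The 4 largest falls after SFP1 were the hexose transporter genes HXT7 (YDR342C, -6.04 ± 0.29) and HXT4 (YHR092C, -5.01 ± 0.20), the hexokinase gene HXK1 (YFR053C, -5.07 ± 0.11) and the acid phosphatase gene PHO12 (YHR215W, -3.84 ± 0.14). In the fixed panel, RPL3 (YOR063W, -1.34 ± 0.07), RPS3 (YNL178W, -0.87 ± 0.06), RPP0 (YLR340W, -0.69 ± 0.08), NOP1 (YDL014W, -1.28 ± 0.08), NOP56 (YLR197W, -1.24 ± 0.06) and RPA190 (YOR341W, -1.28 ± 0.07) fell, TEF1 (YPR080W, -0.27 ± 0.08) and the disaggregase gene HSP104 (YLL026W, -0.39 ± 0.05) fell less, and CIT1 (YNR001C, 0.68 ± 0.07) and TPS1 (YBR126C, 0.53 ± 0.07) rose. HSP12 did not pass (YFL014W, 0.10 ± 0.29, adjusted p = 0.80).

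Over the 5836 genes tested, 1521 rose and 1514 fell (638 with an absolute log2 fold change of at least 1). With library size alone in place of TMM the median of all genes moved by 0.23 and the split became 2516 higher and 889 lower. Adjusted over the list alone, the counts for higher and lower were 5 and 126 for ribosomal proteins, 7 and 117 for ribosome biogenesis, 1 and 36 for translation factors, 0 and 20 for tRNA synthetases, 1 and 13 for the phosphate regulon, 12 and 36 for amino acid biosynthesis, 7 and 40 for mitochondrial ribosomal proteins, and 8 and 0 for meiosis. Of the 14 called lists 12 lost the call with an estimated correlation, while the phosphate regulon (adjusted p = 1.3e-07, 0.0146 with that estimate) and translation factors kept it.

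The remaining lists were not called in the S. cerevisiae deletion, with numbers of higher and lower genes as follows. The induced environmental stress response had 15 and 19 of 46, heat shock chaperones 8 and 12 of 25, trehalose and glycogen 3 and 10 of 20, and TCA and glyoxylate cycles 11 and 5 of 23. Oxidative phosphorylation had 10 and 3 of 38, the proteasome 5 and 5 of 33, sulfur and methionine 7 and 9 of 23, and ergosterol synthesis 11 and 8 of 24. The G1/S list had 5 and 7 of 28, histones 6 and 3 of 10, autophagy 6 and 1 of 18, and hexose transport 3 and 5 of 15. The cell wall list had 12 and 8 of 26, auxotrophic marker genes 3 and 1 of 5, and the list of TORC1 and ribosomal gene regulators 6 and 5 of 23.

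In the S. cerevisiae strain with HA-tagged Sfp1, a protein fused to a short epitope, SFP1 had 509 counts (81.1 ± 12.8 CPM) against 561 in wild type (81.3 ± 6.28 CPM). No gene passed with edgeR, while 319 had an unadjusted p below 0.05 and DESeq2 called 2. The number of calls was 1 without HA replicate A, 2 without HA replicate C and 3 without wild type replicate B. Oxidative phosphorylation genes stood slightly higher as a list (median 0.21, 0 of 38 genes called, 11 adjusted over the list alone, adjusted p = 1.0e-09, 0.149 with an estimated correlation). Ribosome biogenesis stood lower (median -0.07, adjusted p = 5.4e-04, 0.811 with an estimated correlation) and the cell wall list higher (median 0.14, adjusted p = 0.00243, 0.811 with an estimated correlation), each with 0 genes called, also over the list alone. For cytosolic ribosomal proteins the median and the mean lay on opposite sides of 0, with adjusted p = 0.827. Changes of 2-fold were recovered in 86.6% of simulated cases at this depth.

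Set against the HA strain instead of wild type, the S. cerevisiae deletion again had lower ribosomal protein genes (127 fell and 6 rose of 137, also over the list alone, adjusted p = 2.3e-32, 0.137 with an estimated correlation) and lower ribosome biogenesis genes (112 and 7 of 152, 114 and 7 adjusted over the list alone, adjusted p = 7.3e-16, 0.108 with an estimated correlation). The largest changes included HSP26 (YBR072W, 3.81 ± 0.15) upward and HXT7 (YDR342C, -6.39 ± 0.28) and HXK1 (YFR053C, -5.19 ± 0.11) downward. There were 1500 genes higher and 1494 lower, and 2530 and 902 with library size alone (median shift 0.23). Trehalose and glycogen genes fell in this comparison (10 of 20, adjusted p = 0.0303, 0.331 with an estimated correlation). Both comparisons contain the deletion libraries, and the deletion and HA effects against one wild type correlated across genes at 0.189 (covariance 0.0297), where 20 simulations of unchanged strains gave 0.532 (covariance 0.0225).

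**Figure D1:**
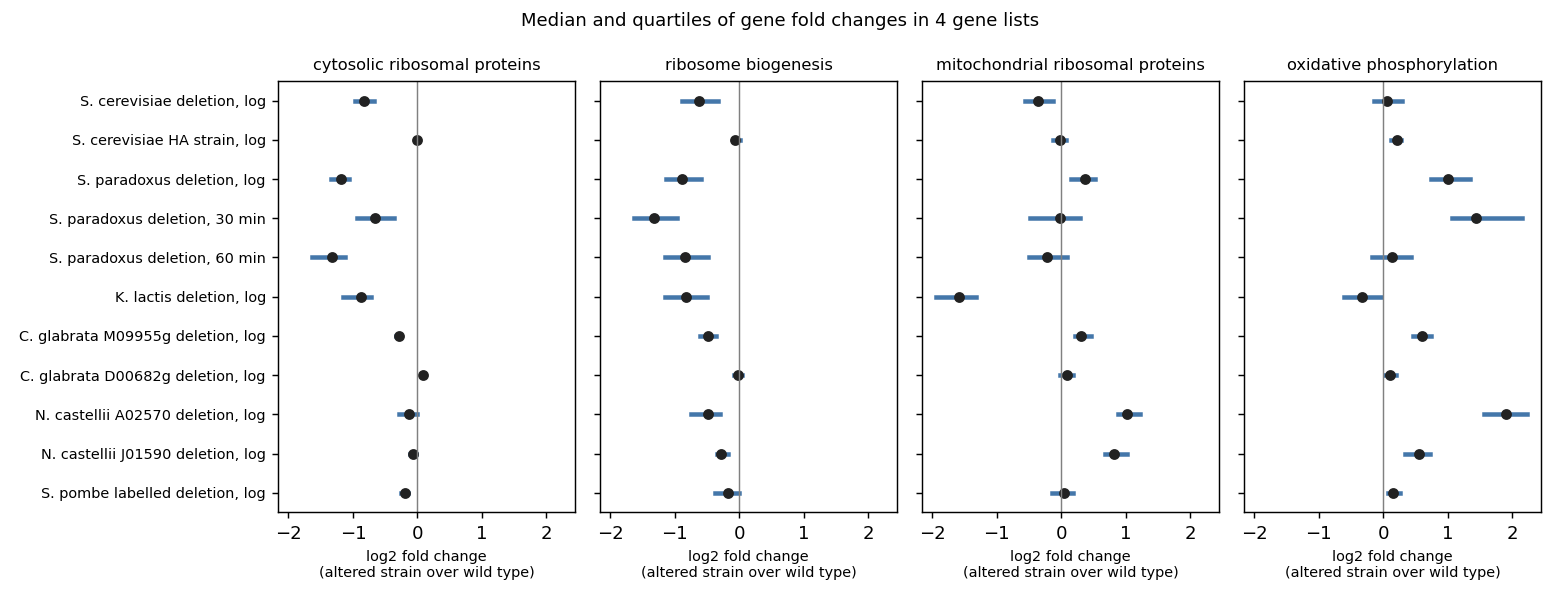
Median (points) and quartiles (bars) of the log2 fold changes, altered strain over wild type, of the genes in 4 lists for the 11 comparisons. Cytosolic ribosomal proteins run from -1.32 in S. paradoxus at 60 min to 0.09 in C. glabrata without CAGL0D00682g, and mitochondrial ribosomal proteins from -1.58 in K. lactis to 1.02 in N. castellii without NCAS0A02570; the N. castellii median of cytosolic ribosomal proteins without NCAS0A02570 and the S. paradoxus lag phase medians of mitochondrial ribosomal proteins change sign with library size alone.

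In S. paradoxus at log phase, SFP1 (Spar_12.540) had 2 counts in the deletion libraries against 675 in wild type (143 ± 15.2 CPM), 0.201% of the wild type level (exact 95% interval 0.0243% to 0.728%). Of 89 cytosolic ribosomal protein genes 88 fell (median -1.18), as with RPL15A/RPL15B (Spar_13.303, -2.17 ± 0.11), and of 150 ribosome biogenesis genes 138 fell and 1 rose, as with NOG2 (Spar_14.417, -1.91 ± 0.10) and NSR1 (Spar_7.497, -1.70 ± 0.11) (adjusted p = 3.9e-46 and 1.3e-25, and 0.0501 and 0.0786 with an estimated correlation). Oxidative phosphorylation rose in 33 of 34 genes, among them the succinate dehydrogenase gene SDH2 (Spar_12.25, 1.90 ± 0.12), and the TCA and glyoxylate list rose in 19 of 25, with the citrate synthase gene CIT2/CIT1 (Spar_3.84, 3.903 ± 0.17) and the isocitrate lyase family gene ICL1 (Spar_16.347, 3.47 ± 0.36) ahead (adjusted p = 2.2e-15 and 2.1e-09, and 0.00526 and 0.0501 with an estimated correlation).

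The libraries of this comparison also differed in mating type. The a-type receptor gene STE2 (Spar_6.56, -5.49 ± 0.14) was at 621 ± 19.8 CPM in wild type and 13.8 ± 2.38 in the deletion, and the alpha-type receptor gene STE3 (Spar_11.71, 6.39 ± 0.17) at 5.82 ± 2.10 and 473 ± 40.9 CPM. The 5 largest rises were STE3 and 4 other genes of mating type: 2 alpha-factor genes, MF(ALPHA)1 or 2 (Spar_16.136, 10.29 ± 0.19) and MF(ALPHA)1 or 2 (Spar_7.201, 6.06 ± 0.23), HMRA2/HMLALPHA2 (Spar_3.145, 9.63 ± 0.62) and HMLALPHA1/MATALPHA1 (Spar_3.146, 7.48 ± 0.63). Among the largest falls were STE2, the a-factor transporter gene STE6 (Spar_11.21, -3.96 ± 0.13) and a member of the FLO10 and FLO11 family of cell surface genes (Spar_9.220, -5.65 ± 0.19). The mating list as a whole had 12 higher and 7 lower of 23 genes (adjusted p = 0.00292, 0.0786 with an estimated correlation). This switch moves with every gene group named here.

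Falls were also called for translation factors (34 of 36, with EFB1 (Spar_1.74, -2.27 ± 0.10)), tRNA synthetases (19 fell and 1 rose of 21, with WRS1 (Spar_15.79, -2.01 ± 0.09)), heat shock chaperones (20 and 3 of 28, with HSC82/HSP82 (Spar_16.84, -2.46 ± 0.14)), glycolysis (18 and 4 of 26), RNA polymerases I and III (20 and 3 of 27) and amino acid biosynthesis (35 and 6 of 52, with LEU4/LEU9 (Spar_15.313, -3.02 ± 0.12), median -0.49 but 0.01 with library size alone). The tRNA synthetases alone kept the call with an estimated correlation, with adjusted p = 0.0519, 0.0276, 0.324, 0.445, 0.0786 and 0.0786 in this order. Rises were called for the iron regulon (19 and 3 down of 29), mitochondrial ribosomal proteins (39 and 3 down of 70), peroxisome (12 of 20, with the acyl-CoA oxidase gene POX1 (Spar_7.61, 3.94 ± 0.29)) and trehalose and glycogen (12 and 1 down of 17), all lost at adjusted p = 0.105, 0.355, 0.324 and 0.29 with an estimated correlation.

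Of 4908 genes 1216 rose and 1602 fell at log phase, and 2885 rose and 676 fell with library size alone (median shift 0.50). Adjusted over the list alone, 89 ribosomal protein genes fell, ribosome biogenesis had 139 lower and 1 higher, and 33 oxidative phosphorylation and 40 mitochondrial ribosomal protein genes rose.

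At 30 min of lag phase SFP1 (Spar_12.540) had 0 counts in the deletion against 258 in wild type (177 ± 18.4 CPM), at least 57.9-fold lower by the same floor. Both strains carried the alpha-type pattern here, with STE2 at 16.6 ± 8.05 CPM in wild type and 21.3 ± 20.2 in the deletion and STE3 at 323 ± 30.0 and 417 ± 40.1 CPM. Ribosome biogenesis fell in 143 of 150 genes and rose in 1 (median -1.32), as with UTP23 (Spar_15.196, -2.74 ± 0.22), and cytosolic ribosomal proteins fell in 74 of 89 and rose in 1 (median -0.66), with adjusted p = 2.2e-31 and 9.5e-15, and 0.0835 and 0.279 with an estimated correlation. tRNA synthetases fell in 19 of 21 (median -2.04), as with WRS1 (Spar_15.79, -2.85 ± 0.13). Oxidative phosphorylation rose in 28 genes and fell in 1 of 34, as with COX9 (Spar_4.213, 4.41 ± 0.90) of cytochrome oxidase and SDH2 (Spar_12.25, 3.53 ± 0.72). The isocitrate lyase family gene with the orthogroup name ICL1 (Spar_16.347, 8.73 ± 0.91) had the largest rise of the TCA and glyoxylate list (13 up and 3 down of 25). For tRNA synthetases, oxidative phosphorylation and the TCA list adjusted p = 0.0303, 0.0246 and 0.365 with an estimated correlation.

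Other rises at 30 min were called for ergosterol synthesis (17 and 1 down of 23), the cell wall (22 and 3 down of 35) and the mating list (15 and 2 down of 23, with the agglutinin gene SAG1 (Spar_10.274, 2.73 ± 0.15)), with adjusted p = 0.26, 0.307 and 0.0835 with an estimated correlation. Translation factors fell in 33 of 36, RNA polymerases I and III in 17 of 27, heat shock chaperones in 19 of 28 and amino acid biosynthesis in 23 of 52 with 13 up (adjusted p = 0.0872, 0.081, 0.381 and 0.307 with an estimated correlation). Among the 5 largest rises were GCV1 (Spar_4.301, 5.81 ± 0.24) of glycine cleavage and the SUN family gene UTH1/SIM1/SUN4 (Spar_10.123, 5.13 ± 0.14); the 2 largest falls after SFP1 were an iron reductase FRE family gene (Spar_14.431, -5.50 ± 0.27) and the isopropylmalate synthase gene LEU4/LEU9 (Spar_15.313, -5.14 ± 0.23).

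In all, 1390 genes rose and 1206 fell at 30 min (1481 by at least 1 on the log2 scale; RLE factors moved the median by -0.11 and turned the split to 1189 higher and 1351 lower, and DESeq2 and 2 other settings turned it too). Adjusted over the list alone, ribosome biogenesis had 145 lower and 1 higher, ribosomal proteins 75 and 1, oxidative phosphorylation 29 higher and 1 lower and the mating list 16 higher and 2 lower. Mitochondrial ribosomal proteins were not called, and their median of -0.02 changes sign with the scaling.

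At 60 min SFP1 (Spar_12.540) had 0 counts in the deletion against 221 in wild type (131 ± 9.08 CPM), at least 80.9-fold lower. Both strains were again alpha-type, with STE3 at 351 ± 36.4 CPM in wild type and 560 ± 59.7 in the deletion. All 89 cytosolic ribosomal protein genes fell (median -1.32), with RPL7A/RPL7B (Spar_16.125, -2.98 ± 0.12) and RPS22B/RPS22A (Spar_10.43, -2.32 ± 0.09) in front, and made up 9.37 ± 0.166% of counts against 18.2 ± 0.372% in wild type. Ribosome biogenesis fell in 131 of 150 genes and rose in 2 (median -0.84), with adjusted p = 2.5e-49 and 1.9e-23, and 0.0452 and 0.142 with an estimated correlation for the 2 lists. Oxidative phosphorylation was not called (median 0.14, 13 up and 2 down of 34), while the TCA and glyoxylate list rose in 15 of 25 genes, again with ICL1 (Spar_16.347, 5.32 ± 0.70) first (adjusted p = 0.181 with an estimated correlation).

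tRNA synthetases fell in 19 of 21 genes, translation factors in 34 of 36, RNA polymerases I and III in 17 of 27 and heat shock chaperones in 15 of 28 (adjusted p = 0.0318, 0.0944, 0.121 and 0.776 with an estimated correlation). The cell wall list rose in 21 of 35, the iron regulon in 13 of 29 and the mating list in 16 of 23, with SAG1 at 2.92 ± 0.14 (Spar_10.274), and adjusted p = 0.181, 0.776 and 0.0452 with an estimated correlation. Leading rises were UTH1/SIM1/SUN4 (Spar_10.123, 5.31 ± 0.22), GCV1 (Spar_4.301, 4.87 ± 0.30) and GCV3 (Spar_1.23, 4.04 ± 0.22), and the leading fall after SFP1 was SDO1 (Spar_12.96, -4.28 ± 0.36), which acts in 60S subunit maturation.

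At 60 min 1263 genes rose and 1229 fell, and with library size alone 1913 rose and 809 fell (median shift 0.28). TEF1 or TEF2 (Spar_16.436) had 0.03 ± 0.11 with adjusted p = 0.84 and a sign that changes with the scaling. The counts adjusted over the list alone were 89 lower for ribosomal proteins, 132 lower and 2 higher for ribosome biogenesis, and 23 higher and 3 lower for the cell wall.

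Phase dependence of the S. paradoxus deletion was tested as an interaction. Against log phase, the effect at 30 min was less negative for ribosomal proteins (64 higher and 1 lower of 89, median 0.54). Library size alone shifted genes there by -0.45. Ribosome biogenesis was more negative (76 lower and 7 higher of 150, median -0.49) and ergosterol synthesis higher (19 of 23). Adjusted p was 1.1e-11, 9.0e-14 and 7.7e-10, and 0.398, 0.396 and 0.155 with an estimated correlation. The effect at 60 min was lower for oxidative phosphorylation (27 of 34, median -1.001) and mitochondrial ribosomal proteins (28 lower and 1 higher of 70, median -0.59) and higher for the cell wall (21 up and 2 down of 35), with adjusted p = 1.1e-14, 9.0e-07 and 9.4e-09, and 0.00541, 0.558 and 0.276 with an estimated correlation. In both tests wild type changed from a-type to alpha-type between log and lag phase: STE2 (Spar_6.56) stood at 621 ± 19.8 CPM at log phase and 16.6 ± 8.05 and 14.0 ± 3.74 CPM at 30 and 60 min.

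Ribosomal proteins had 1 gene higher and 20 lower in the effect at 60 min (median -0.17, 1 and 20 adjusted over the list alone, adjusted p = 1.7e-07, 0.62 with an estimated correlation), and ribosome biogenesis was not called, with median 0.01, a negative mean and a sign that changes with library size alone. With p-values adjusted over the list alone, ribosomal proteins had 70 higher and 2 lower at 30 min, ribosome biogenesis 9 and 87, and oxidative phosphorylation at 60 min 1 and 27. The mating list was not called in either, and there the median (0.36 at 30 min, negative with library size alone) was positive and the test negative.

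Genes with a different effect numbered 1556 at 30 min (988 higher, 568 lower) and 1239 at 60 min (792 and 447). Scaling turned the first split to 434 and 1272 with library size alone (median shift -0.45). RLE factors gave 705 and 826 (-0.19, and -0.21 with only the groups compared). The second split became 494 and 847 (-0.21) and 611 and 636 (-0.11).

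The 2 lag phase times were then compared directly, in groups that share a mating type. In wild type from 30 to 60 min, oxidative phosphorylation rose in 30 of 34 genes (median 1.71), as with SDH2 (Spar_12.25, 4.80 ± 0.53) and COX9 (Spar_4.213, 4.67 ± 0.79), and cytosolic ribosomal proteins rose in 54 and fell in 5 of 89 (median 0.27), with adjusted p = 1.9e-24 and 2.6e-07, and 5.3e-04 and 0.376 with an estimated correlation. Genes of ribosome biogenesis fell in 138 of 150 (median -0.80), and the phosphate regulon in 8 of 10, as with the polyphosphate synthesis gene VTC3/VTC2 (Spar_16.319, -3.74 ± 0.15) (adjusted p = 3.6e-33 and 4.3e-09, and 0.085 and 8.7e-04 with an estimated correlation). In the deletion, ribosomal proteins fell in 77 of 89 (median -0.48, shifted by 0.42 with library size alone). Oxidative phosphorylation rose in 15 and fell in 1 (median 0.41), and histones rose in 6 of 7, as with HTA2/HTA1 (Spar_4.539, 2.12 ± 0.17). Adjusted p was 4.6e-21, 1.4e-04 and 1.1e-06, and 0.192, 0.151 and 0.0315 with an estimated correlation.

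The difference in course was tested too. Relative to wild type, the deletion lost ground from 30 to 60 min in ribosomal proteins (78 of 89 lower, median -0.74) and oxidative phosphorylation (27 of 34 lower, median -1.43, as with COX9 (Spar_4.213, -4.51 ± 0.996)) and gained in ribosome biogenesis (63 higher and 2 lower of 150, median 0.48), with adjusted p = 7.9e-36, 4.8e-18 and 9.4e-17, and 0.172, 0.00231 and 0.253 with an estimated correlation. Adjusted over the list alone these counts were 84 lower and 1 higher, 28 lower, and 80 higher and 4 lower.

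Histones also rose in wild type (5 of 7, adjusted p = 2.9e-04, 0.0872 with an estimated correlation), and amino acid biosynthesis fell in 30 of 52 genes (5.5e-08, 0.0188). The phosphate regulon fell in the deletion too (6 of 10, adjusted p = 0.00407 with an estimated correlation). Ribosome biogenesis in the deletion fell in 39 genes (adjusted p = 2.1e-05, 0.569 with an estimated correlation), but its median of -0.27 was 0.15 with library size alone.

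Here 828 genes rose and 972 fell in wild type, 391 and 722 in the deletion (736 in all without deletion replicate B at 30 min). In the difference 368 were higher and 385 lower. Library size alone gave 1326 and 710, 1714 and 301, and 728 and 281, with median shifts of 0.18, 0.42 and 0.23.

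**Figure D2:**
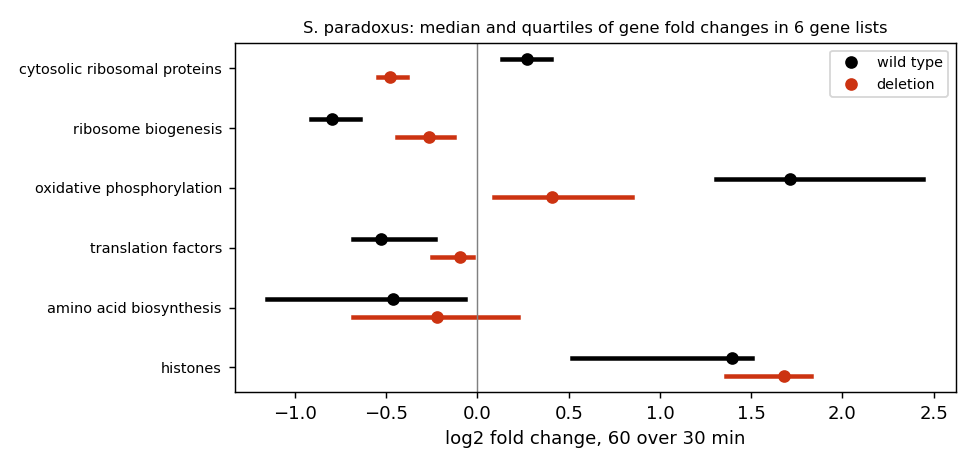
Median (points) and quartiles (bars) of the log2 fold changes from 30 to 60 min of lag phase in 6 gene lists of S. paradoxus, wild type in black and deletion in red. Cytosolic ribosomal proteins have medians of 0.27 in wild type and -0.48 in the deletion and oxidative phosphorylation 1.71 and 0.41; the deletion medians of ribosome biogenesis and amino acid biosynthesis change sign with library size alone.

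**Figure D3:**
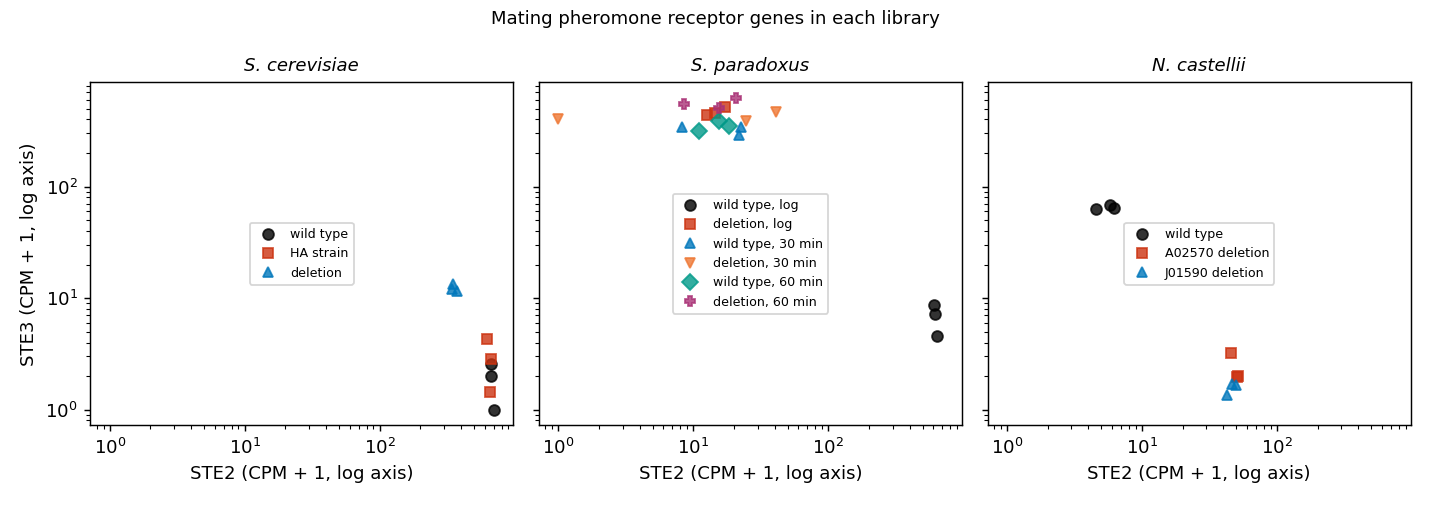
STE2 against STE3, both as CPM plus 1 on log axes, with 1 point per library, in S. cerevisiae, S. paradoxus and N. castellii.

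In C. glabrata, deletion of CAGL0D00682g left 0 counts of that gene against 265 in wild type (39.2 ± 5.11 CPM), at least 96.2-fold lower, and its paralog CAGL0M09955g had 44.3 ± 2.22 against 42.7 ± 6.26 CPM (adjusted p = 0.949). Of 4766 genes 18 rose and 9 fell, the deleted gene included, and 5 of these changed by at least 1 on the log2 scale. Of the largest changes as defined above, the rises were led by FRM2/HBN1 (CAGL0B00990g, 0.89 ± 0.16), of the nitroreductase family, and MIM1 (CAGL0F01221g, 0.77 ± 0.18), of the mitochondrial outer membrane; the falls after the deleted gene were led by the arginase gene CAR1 (CAGL0J07062g, -0.46 ± 0.07, adjusted p = 2.7e-05) and the glucan synthase gene GSC2/FKS1/FKS3 (CAGL0K04037g, -0.46 ± 0.09). The largest subunit gene of RNA polymerase I fell slightly (RPA190 (CAGL0E05500g, -0.26 ± 0.06, adjusted p = 0.00829)).

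Cytosolic ribosomal proteins stood slightly higher as a list (median 0.09, adjusted p = 1.6e-06, 0.653 with an estimated correlation), with 0 of 84 genes called by edgeR and 0 over the list alone. Oxidative phosphorylation had 1 called gene of 39, SDH9/SDH1 (CAGL0J00847g, 0.35 ± 0.07) (2 adjusted over the list alone, adjusted p = 0.00286, 0.156 with an estimated correlation). Histones had 1 of 12 (5 over the list alone, 2.5e-04 and 0.603), and mitochondrial ribosomal proteins 0 (median 0.09, 0.0275 and 0.603). With library size alone 15 genes rose and 4 fell.

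Deletion of the other paralog left 0 counts of CAGL0M09955g against 290 (42.7 ± 6.26 CPM), at least 109.6-fold lower, and CAGL0D00682g rose slightly (0.34 ± 0.13, adjusted p = 0.0307). Ribosome biogenesis fell in 135 of 156 genes (median -0.48), as with RCL1 (CAGL0E02343g, -0.99 ± 0.13) of small subunit processing, and cytosolic ribosomal proteins fell in 77 and rose in 1 of 84 (median -0.29), with adjusted p = 6.7e-35 and 4.2e-18, and 0.00232 and 0.151 with an estimated correlation. Oxidative phosphorylation rose in 32 of 39 genes (median 0.60), as with NDE1/NDE2/NDI1 (CAGL0B02431g, 1.23 ± 0.11) and SDH2 (CAGL0C03223g, 1.09 ± 0.15), and mitochondrial ribosomal proteins in 29 of 75. Translation factors fell in 37 of 38, tRNA synthetases in 20 of 22 and RNA polymerases I and III in 16 of 29.

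Rises were also called for TCA and glyoxylate cycles (12 up and 2 down of 26, with the succinyl-CoA ligase genes LSC1 (CAGL0I07139g, 1.35 ± 0.10) and LSC2 (CAGL0F08107g, 1.35 ± 0.10)), histones (10 of 12), trehalose and glycogen (9 and 1 down of 17) and peroxisome (7 of 24), and all 4 calls ended at adjusted p = 0.0617, 0.193, 0.0764 and 0.151 with an estimated correlation. The largest single rise was the phospholipid methyltransferase gene CHO2 (CAGL0E03201g, 1.63 ± 0.14). In all 720 genes rose and 885 fell, 83 by at least 1 on the log2 scale; DESeq2 called 350 and 687, and library size alone gave 1275 and 468 (median shift 0.16). With p-values adjusted over the list alone, 139 ribosome biogenesis genes fell, 79 ribosomal protein genes fell and 2 rose, and 35 oxidative phosphorylation genes rose. The calls for oxidative phosphorylation (adjusted p = 4.3e-15, 0.00221 with an estimated correlation), mitochondrial ribosomal proteins (1.3e-07, 0.0222), translation factors, tRNA synthetases and RNA polymerases held with it.

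Compared with each other, the strain without CAGL0D00682g exceeded the one without CAGL0M09955g in 143 of 156 ribosome biogenesis genes (145 adjusted over the list alone, median 0.48) and 82 of 84 ribosomal protein genes (82 over the list alone, median 0.36), and was below it in 31 of 39 oxidative phosphorylation genes (33 over the list alone, median -0.51), with adjusted p = 2.7e-37, 2.1e-27 and 6.0e-13, and 0.00192, 0.0872 and 0.00192 with an estimated correlation. There were 817 genes higher and 586 lower, 623 and 275 by DESeq2, and 454 and 1155 with library size alone (median shift -0.15). The effects of both deletions against their shared wild type correlated across genes at 0.367 (covariance 0.0306), and simulations of unchanged strains gave 0.534 (0.0169).

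In N. castellii, the first strain carried a deletion of NCAS0A02570, which had 5 counts left against 632 in wild type (67.8 ± 2.13 CPM), -6.23 ± 0.27 on the log2 scale; the paralog NCAS0J01590 did not pass (0.16 ± 0.16, adjusted p = 0.437). All 39 oxidative phosphorylation genes rose (median 1.90), as with SDH2 (NCAS0C05870, 2.70 ± 0.17), as did 74 of 75 mitochondrial ribosomal protein genes (median 1.02), as with MRPL25 (NCAS0I02230, 2.13 ± 0.35), and 23 of 27 TCA and glyoxylate genes, with IDP1/IDP2/IDP3 (NCAS0A08720, 5.54 ± 0.39), of isocitrate dehydrogenase, first. Ribosome biogenesis fell in 116 of 153 genes and rose in 2 (median -0.48), as with NOP1 (NCAS0I01890, -1.22 ± 0.09) and NSR1 (NCAS0A05890, -1.16 ± 0.08).

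Translation factors fell in 30 of 39 genes, tRNA synthetases in 21 of 22, heat shock chaperones in 19 of 27, RNA polymerases I and III in 16 of 29, the iron regulon in 11 of 17 and the proteasome in 13 of 34 (adjusted p = 0.0118, 0.0169, 0.14, 0.0239, 0.138 and 0.172 with an estimated correlation). Cytosolic ribosomal proteins fell in 42 and rose in 4 of 103, with a median of -0.13 that was 0.04 with library size alone (adjusted p = 3.5e-04, 0.542 with an estimated correlation). Wild type was alpha-type and this strain a-type: STE2 rose from 4.55 to 48.1 CPM (3.38 ± 0.18, NCAS0C03840), and the alpha-factor gene MF(ALPHA)1 or 2 (NCAS0D03650, -5.87 ± 0.16), SAG1 (NCAS0A01430, -4.26 ± 0.15) and, outside the rule for largest changes, STE3 (NCAS0B08390, -5.50 ± 0.24) fell, while the agglutinin gene AGA1/FIG2 (NCAS0A05530, 3.85 ± 0.18) was the largest rise. The mating list itself was not called (6 up and 10 down of 23), and this switch moves with every gene group of the comparison. The stress gene HSP12 (NCAS0C03960, 2.84 ± 0.15) also rose.

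In all 1140 genes rose and 1090 fell of 5338 (504 by at least 1 on the log2 scale), and 1672 and 548 with library size alone (median shift 0.17). Adjusted over the list alone, all 39 oxidative phosphorylation and all 75 mitochondrial ribosomal protein genes rose, 118 ribosome biogenesis genes fell and 2 rose, and 42 ribosomal protein genes fell and 4 rose. Camera gave adjusted p = 1.2e-26 for oxidative phosphorylation, 1.4e-26 for mitochondrial ribosomal proteins and 2.1e-21 for ribosome biogenesis, and 0.0169, 0.0135 and 0.042 with an estimated correlation.

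The second N. castellii strain had 0 counts of NCAS0J01590 against 221 in wild type (23.6 ± 1.12 CPM), at least 70.0-fold lower, and NCAS0A02570 did not pass (-0.07 ± 0.11, adjusted p = 0.682). Mitochondrial ribosomal proteins rose in 74 of 75 genes (median 0.82), as with MRPL25 (NCAS0I02230, 1.81 ± 0.34), oxidative phosphorylation in 24 of 39 (median 0.55) and the TCA list in 18 of 27 (adjusted p = 7.5e-33, 2.9e-11 and 6.2e-07, and 0.0212, 0.083 and 0.0212 with an estimated correlation). The iron regulon fell in 14 of 17 genes, as with the multicopper oxidase gene FET3/FET5/GMC1 (NCAS0A08200, -2.69 ± 0.17) and the copper transporter gene CCC2 (NCAS0C05330, -2.28 ± 0.14). Genes of ribosome biogenesis fell in 69 of 153 and rose in 1 (median -0.28), while cytosolic ribosomal proteins had 6 lower and 2 higher of 103 (median -0.07), with adjusted p = 6.8e-16 and 0.0054, and 0.083 and 0.723 with an estimated correlation.

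Trehalose and glycogen genes rose in 13 of 19 cases, and heat shock chaperones fell in 16 of 27, tRNA synthetases in 13 of 22 and translation factors in 16 of 39, all lost at adjusted p = 0.104, 0.183, 0.083 and 0.0733 with an estimated correlation. This strain was a-type as well, with STE2 at 45.5 CPM, and the mating list fell (5 up and 10 down of 23, adjusted p = 0.0171, 0.104 with an estimated correlation). Among its leading changes were the alpha-factor gene MF(ALPHA)1 or 2 (NCAS0D03650, -6.53 ± 0.15) downward and STE2 (NCAS0C03840, 3.29 ± 0.17) upward; outside that rule STE3 (NCAS0B08390, -6.72 ± 0.25) fell too. Other leading changes were YPR127W (NCAS0A11670, 3.89 ± 0.14) and, downward, a hexose transporter family gene (NCAS0F03100, -3.35 ± 0.13); HSP12 (NCAS0C03960, -0.51 ± 0.15) fell.

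There were 790 genes higher and 603 lower (260 by at least 1 on the log2 scale), and 526 and 1174 with library size alone (median shift -0.15). Adjusted over the list alone, 74 mitochondrial ribosomal protein genes and 27 oxidative phosphorylation genes rose, 89 ribosome biogenesis genes fell and 1 rose, and 2 ribosomal protein genes fell and 2 rose. The iron regulon kept its call (adjusted p = 5.2e-14, 0.0279 with an estimated correlation). The call for ribosomal proteins also ended without wild type replicate A (adjusted p = 0.0524).

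Between the 2 N. castellii deletions, which share the a-type pattern, oxidative phosphorylation was higher without NCAS0A02570 in 38 of 39 genes (also over the list alone, median 1.32), as with ATP18 (NCAS0A06260, 2.12 ± 0.25) of the ATP synthase, and tRNA synthetases were lower in 20 of 22 (21 lower and 1 higher over the list alone). Translation factors were lower in 26 of 39. HSP12 (NCAS0C03960, 3.35 ± 0.15) was higher. Ribosome biogenesis was lower in 64 and higher in 3 of 153 genes (75 and 4 over the list alone, adjusted p = 0.173 with an estimated correlation), with a median of -0.25 that was 0.08 with library size alone, and ribosomal proteins were not called (median -0.06, 0.27 with library size alone, adjusted p = 0.0568).

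There were 602 genes higher and 687 lower, against 2174 and 181 with library size alone (median shift 0.33). Adjusted p was 1.3e-32 for oxidative phosphorylation (0.0168 with an estimated correlation), 6.0e-11 for tRNA synthetases (0.0226) and 5.9e-09 for ribosome biogenesis. Against wild type both deletions correlated at 0.693 (covariance 0.235, same sign in 74.2% of genes). Simulated unchanged strains gave 0.450 (0.0155, 65.2%) without a mating-type switch. The excess has no tested cause.

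In K. lactis, SFP1 (KLLA0B03047g) had 0 counts in the deletion against 1006 in wild type (135 ± 9.996 CPM), at least 364-fold lower. Cytosolic and mitochondrial ribosomal protein genes fell together: all 59 of the first (median -0.87), as with RPS22B/RPS22A (KLLA0B07931g, -3.93 ± 0.09), and all 60 of the second (median -1.58), as with RSM23 (KLLA0B02222g, -2.58 ± 0.11) (adjusted p = 8.1e-17 and 2.4e-19, and 0.243 and 0.0514 with an estimated correlation). Ribosome biogenesis fell in 113 of 125 genes and rose in 2 (median -0.83), as with NOP58 (KLLA0F08613g, -2.10 ± 0.08) (adjusted p = 2.2e-17, 0.0813 with an estimated correlation). Induced stress genes rose in 23 and fell in 6 of 37 cases, with the largest rises of the whole comparison, HSP12 (KLLA0D07634g, 6.90 ± 0.09, adjusted p = 1.9e-19) and MSC1 (KLLA0D10439g, 6.68 ± 0.15), among them (adjusted p = 0.0024, 0.255 with an estimated correlation for the list).

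Further falls were called for translation factors (28 of 30), tRNA synthetases (19 of 19), amino acid biosynthesis (31 of 40), heat shock chaperones (13 of 15, with the mitochondrial chaperonin gene HSP60 (KLLA0F09449g, -2.71 ± 0.06)), RNA polymerases I and III (17 of 24), the proteasome (18 of 25) and oxidative phosphorylation (17 fell and 2 rose of 28). The first 2 kept their call with an estimated correlation, and adjusted p = 0.032, 0.032, 0.0585, 0.0694, 0.0813, 0.243 and 0.0902 in this order. Rises were called for peroxisome and fatty acid oxidation (11 of 14, with the catalase gene CTT1/CTA1 (KLLA0D14685g, 5.43 ± 0.11)), the G1/S list (16 of 26) and autophagy (10 of 16), all lost at adjusted p = 0.0694, 0.255 and 0.173 with an estimated correlation. Among the leading falls was an alcohol dehydrogenase family gene (KLLA0B09064g, -6.20 ± 0.10). TEF1 or TEF2 (KLLA0B08998g) did not pass (-0.02 ± 0.04, adjusted p = 0.73), and stood at 0.21 with library size alone.

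Of 4941 genes 1634 rose and 1645 fell (935 by at least 1 on the log2 scale), and 2140 and 1064 with library size alone (median shift 0.23). The counts adjusted over the list alone equal those over all genes for both ribosomal protein lists and for ribosome biogenesis.

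In S. pombe, the libraries labelled deletion still held sfp1 counts. The gene (SPAC16.05c, build ASM294v2, chromosome I, 4431869 to 4434513, minus strand) had 98, 106 and 22 counts in them against 169, 100 and 134 in wild type, that is 40.5 ± 8.74 and 75.6 ± 13.5 CPM, 57.0% of the wild type level (exact 95% interval 48.2% to 67.2%), with a log2 fold change of -0.83 ± 0.17 (adjusted p = 0.0155). The M-type mating gene mat1-Mc had 0 counts in them against 43, 39 and 55 in wild type (at most 2.77% of wild type), and the M-factor gene mfm2 had 10 against 179, and this difference in mating-type genes stands beside every gene group below. Ribosome biogenesis fell in 38 of 153 genes and rose in 4 (median -0.18), as with RIO1 (SPAC10F6.10.1, -1.21 ± 0.18) and the panel gene NOP56 (SPBC646.10c.1, -0.90 ± 0.09), and purine and pyrimidine synthesis fell in 14 of 26 (adjusted p = 2.1e-06 and 2.1e-06, and 0.355 and 0.164 with an estimated correlation).

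Cytosolic ribosomal proteins fell in 12 of 143 genes (median -0.20), and 131 did not pass (adjusted p = 6.5e-09, 0.784 with an estimated correlation). Translation factors fell in 15 of 40, tRNA synthetases in 11 of 22, amino acid biosynthesis in 12 of 53, RNA polymerases I and III in 6 of 28 and heat shock chaperones in 5 of 20 (adjusted p = 0.164, 0.164, 0.164, 0.164 and 0.253 with an estimated correlation). Oxidative phosphorylation rose in 3 of 35 and the stress list in 9 of 41, as with the catalase gene CTT1/CTA1 (SPCC757.07c.1, 1.24 ± 0.12) (adjusted p = 0.405 and 0.355 with an estimated correlation). Among the 5 largest rises were SMN1 (SPBPB2B2.06c.1, 6.94 ± 0.17) and the galactose pathway genes of the GAL10 family (SPBPB2B2.12c.1, 2.48 ± 0.58) and GAL7 (SPBPB2B2.10c.1, 1.63 ± 0.23), and among the largest falls were GIS2 (SPAC683.02c.1, -3.08 ± 0.26) and the adenine deaminase gene AAH1 (SPBC1198.02.1, -2.27 ± 0.11).

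Of 5296 genes 169 rose and 360 fell (126 by at least 1 on the log2 scale), 343 and 237 with library size alone (median shift 0.12). The total of 529 was 278 without replicate A and 277 without replicate B of the libraries labelled deletion and 350 without wild type replicate C. With p-values adjusted over the list alone, 58 ribosome biogenesis genes fell and 8 rose, and 12 ribosomal protein genes fell. Of the 10 lists called none kept its call with an estimated correlation.

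Across species, each difference from wild type was tested against that in the S. cerevisiae deletion on orthogroups with 1 gene in each. In S. paradoxus, N. castellii and S. pombe these tests include the difference in mating type between wild type and altered libraries, and the S. pombe libraries labelled deletion are not shown to lack sfp1. Mitochondrial ribosomal proteins differed in 6 of the 7 tests with an estimated correlation. Relative to S. cerevisiae they were higher in S. paradoxus (49 of 64 genes, 53 adjusted over the list alone, median 0.80), in N. castellii without NCAS0A02570 (65 of 69, 66 over the list alone, 1.30) or NCAS0J01590 (60 up and 1 down of 69, 61 and 1 over the list alone, 1.15), and in C. glabrata without CAGL0M09955g (45 of 69, 49 over the list alone, 0.67) or CAGL0D00682g (25 up and 4 down, 29 and 4 over the list alone, 0.45). They were lower in K. lactis (52 down and 1 up of 56, 52 and 1 over the list alone, -1.29). With an estimated correlation the adjusted p-values were, in this order, 0.0207, 0.0032, 1.2e-04, 0.00215, 0.0243 and 4.6e-04, and 0.0522 in S. pombe.

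The other lists that passed with an estimated correlation were all higher than in S. cerevisiae, and adjusted p with that estimate follows each count. Several of these lists fell in the S. cerevisiae deletion itself, and that fall enters each difference. Oxidative phosphorylation was higher in S. paradoxus (23 of 23, 0.0207) and in N. castellii without NCAS0A02570 (27 of 27, 0.0265), as were TCA and glyoxylate cycles (7 of 10, 0.0485, and 9 of 12, 0.0432). The phosphate regulon was higher in S. paradoxus (5 of 7, 0.0207), in C. glabrata without CAGL0D00682g (6 of 6, 0.0243) or CAGL0M09955g (6 of 6, 0.0181) and in N. castellii without NCAS0A02570 (5 of 5, 0.0426). Induced stress genes were higher in S. paradoxus (9 up and 1 down of 15, 0.0485) and K. lactis (10 of 10, 0.0334). For translation factors this held in C. glabrata without CAGL0D00682g (24 of 25, 0.00365) or CAGL0M09955g (18 up and 1 down of 25, 0.0181), in N. castellii without NCAS0J01590 (21 of 24, 0.0205) and in S. pombe (20 of 24, 0.00621), and for tRNA synthetases in S. pombe (15 of 18, 0.0289) and without CAGL0D00682g (19 of 19, 0.0243). Ribosome biogenesis (103 up and 4 down of 142, 0.0233) and RNA polymerases I and III (14 up and 2 down of 26, 0.0424) were higher without CAGL0D00682g. The number of orthogroups with a different effect was 995 of 3276 in S. paradoxus (449 higher, 546 lower), 1128 of 3279 and 1205 of 3281 in C. glabrata without CAGL0D00682g and CAGL0M09955g, 1381 of 3264 and 1353 of 3257 in N. castellii without NCAS0A02570 and NCAS0J01590, 1409 of 2642 in K. lactis and 909 of 2476 in S. pombe. Library size alone turned 5 of the 7 splits: to 566 higher and 390 lower in S. paradoxus, from 639 and 489 to 380 and 866 without CAGL0D00682g, from 726 and 655 to 657 and 758 without NCAS0A02570, from 757 and 596 to 576 and 836 without NCAS0J01590, and from 466 and 443 to 385 and 520 in S. pombe.

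Similarity of the mutant effects was described over 55 pairs of comparisons, 3 of which share wild type libraries. The S. cerevisiae deletion was closest to S. paradoxus at log phase among the other species (r = 0.645 and rho = 0.591 across 3086 orthogroups), with 573 shared falls where 267 were expected (Fisher's exact test, Benjamini-Hochberg p = 8.1e-149) and 410 shared rises against 180 (8.9e-102). Next by r came K. lactis (r = 0.407 and rho = 0.394, 471 shared falls against 259 and 229 shared rises against 162), C. glabrata without CAGL0M09955g (0.270 and 0.262, 378 against 162 and 135 against 98.3) and the S. pombe libraries labelled deletion (0.193 and 0.160, 116 against 52.1 and 20 against 14.0). In N. castellii rho was higher than r: 0.193 against 0.138 without NCAS0A02570 (379 shared falls against 174 and 156 shared rises against 160.03), which by rho places it above S. pombe, and 0.125 against -0.001 without NCAS0J01590 (195 against 90.9 and 88 against 104). Of the genes called in both, 262 of 797 and 203 of 486 had opposite signs in these 2 pairs. C. glabrata without CAGL0D00682g gave an r of 0.033. Outside the ribosomal lists r was 0.617, 0.372, 0.208, 0.156, 0.083, -0.045 and 0.032 in the same order. These are correlations across genes, which are not independent replicates.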

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

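The 3 comparisons of 60 with 30 min and all tests that weigh the 3 patterns in this part were chosen only after results were seen; the other differences between groups, the species differences and the splits of the samples were planned.

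In S. paradoxus the difference between deletion and wild type libraries varied between times by a test of that difference itself, in 1556 genes at 30 min against log phase, 1239 at 60 min against log phase and 753 at 60 against 30 min. The real split gave the most genes each time (1 of 100 as large), with 963, 398 and 380 in the highest other. The others mix deletion and wild type, so chance stays open. The first 2 counts are not shown to come from the phase, since wild type libraries also changed mating type between log and lag phase.

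Differences from wild type also departed from that in the S. cerevisiae deletion. The number of orthogroups was 995 in S. paradoxus, 1128 in C. glabrata without CAGL0D00682g, 1205 without CAGL0M09955g, 1381 in N. castellii without NCAS0A02570, 1353 without NCAS0J01590, 1409 in K. lactis and 909 in the S. pombe libraries labelled deletion. The highest other of 100 splits gave 279, 1099, 638, 428, 769, 707 and 655 in the same order. These splits also mix altered and wild type libraries, so chance stays open here too. Without CAGL0D00682g the margin is narrow: leaving out 1 library moved the real count between 1008 and 1135, a range that holds the 1099 of the other split.

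For comparisons of 3 with 3 libraries the 10 possible splits are too few for a share under 0.05. The real split gave 3035 genes in the S. cerevisiae deletion, 2994 for deletion against HA, 2818 in S. paradoxus at log phase, 2492 at 60 min, 1605 without CAGL0M09955g, 1403 between the C. glabrata strains, 2230 without NCAS0A02570, 1393 without NCAS0J01590, 1289 between the N. castellii strains, 3279 in K. lactis, 529 in S. pombe and 1800 in S. paradoxus wild type at 60 against 30 min, where the highest other split gave 0. It gave 2596 against 2 in S. paradoxus at 30 min, 27 against 2 without CAGL0D00682g and 1113 against 112 in the S. paradoxus deletion at 60 against 30 min. For the HA strain it gave 0 with edgeR (319 at an unadjusted p below 0.05, 2 with DESeq2), as large in 10 of 10 splits, and the highest other split gave 1.

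The deposited microarray ratios enter no comparison of the report and are described here without a test. With the sign turned to deletion over wild type, a list of at least 20 orthogroups was flagged per strain. Its median was 1.59 and 1.49 for the proteasome in the 2 S. cerevisiae strain backgrounds at 30 min. It was 0.83 for TCA and glyoxylate cycles without CAGL0D00682g at 90 min and 1.60 for the proteasome without CAGL0M09955g at 30 min. It was -0.93 for tRNA synthetases without NCAS0A02570, -2.40 for cytosolic ribosomal proteins without NCAS0J01590, -1.54 for the G1/S list in K. lactis and -0.67 for RNA polymerases I and III in S. pombe, each at 30 min.

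The S. pombe libraries labelled deletion hold sfp1 counts, at least 22 in each library. A mix with the sequenced wild type is excluded, since mat1-Mc and mfm2 stay under 10.7% of it (the higher upper limit) while sfp1 stands at 57.0%. Wild type cells without mat1-Mc stay open. Swapped labels, for 1 library or all, stay open. The lowest sfp1 count under wild type is 100, but no library lacks sfp1, so this cannot decide. A strain or construct that still transcribes sfp1 in whole or part stays open. The mat1-Mc counts set the libraries apart from the wild type strain. Array ratios of sfp1 from -8.07 to -7.50 set them apart from the array samples, taken at other growth phases and in a unit not stated. Neither says what the libraries hold. No biological explanation was tested.

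Mating-type genes differ between wild type and deletion in S. paradoxus at log phase and in N. castellii. For S. paradoxus the deletion itself is excluded as the cause, since STE3 in wild type at 30 min reached 68.3% of its level in the deletion at log phase. Labels swapped between wild type and deletion libraries are excluded by the 2 SFP1 counts of the deletion libraries at log phase. A strain difference besides the deletion may explain it, since STE2 differed 37.4-fold between wild type libraries at log phase and 30 min. In N. castellii the deletion itself cannot be told apart from a strain difference: the array ratios of the mating-type genes reach no farther than -0.76 from 0, but the arrays were taken at other growth phases.

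Mitochondrial ribosomal proteins fell in K. lactis and rose in N. castellii. Scaling is excluded, since the lowest N. castellii median over the scalings was 0.66 and the K. lactis median stayed below 0. Gene length bias is excluded: of 10000 lists matched on coding length the lowest median in K. lactis was -0.46 and the highest in N. castellii 0.47. In N. castellii a strain difference besides the deletion cannot be told apart from an effect of the deletion, because the highest median of the list in the array ratios was 0.00485 but the arrays were taken at other growth phases. A difference between species stays open as a hypothesis, which may apply beside a strain difference.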

How the results depend on the processing

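The tests of leaving out ribosomal RNA genes, of thinning the S. paradoxus libraries to lag phase depth and of leaving out the S. paradoxus library of lowest depth were chosen only after results were seen. In each setting 1 choice was changed, except that DESeq2 brings its own scaling, filtering and test. Where only part of the libraries or genes entered, fewer were tested by construction; beyond that the cause was not tested for any change given here. D00682g, M09955g, A02570 and J01590 stand for the strains without CAGL0D00682g, CAGL0M09955g, NCAS0A02570 and NCAS0J01590.

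Counts of genes stayed within 1.5 times the reported count in all 26 comparisons with RLE factors, in all 26 with TMM factors computed without the ribosomal lists, in all 26 without the filter, in all 17 fitted on the groups compared only, in all 8 with thinned libraries and in all 7 without ribosomal RNA genes. The larger of the numbers of higher and lower genes changed sides in 17 of the 26 with library size alone, 8 with RLE factors, 5 with TMM factors without the ribosomal lists, 7 with DESeq2 and 11 with a minimum absolute log2 fold change of 1. With library size alone the total became 2015 (deletion 60 against 30 min) and 2355 (both N. castellii strains). DESeq2 gave 2 (HA strain), 1037 (C. glabrata M09955g) and 898 (both C. glabrata strains). The replicate letter as a block gave 3 (HA strain); correlations between residuals of the same letter, checked in 16 comparisons, ran from -0.174 to 0.0865.

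A minimum absolute log2 fold change of 1 left 638 (S. cerevisiae deletion), 614 (deletion against HA), 816 (S. paradoxus log phase), 1481 (S. paradoxus 30 min), 1077 (S. paradoxus 60 min), 737 (effect at 30 min against log phase), 480 (effect at 60 min against log phase), 565 (wild type 60 against 30 min), 331 (deletion 60 against 30 min), 287 (effect at 60 against 30 min), 5 (C. glabrata D00682g), 83 (C. glabrata M09955g), 62 (both C. glabrata strains), 504 (N. castellii A02570), 260 (N. castellii J01590), 204 (both N. castellii strains), 935 (K. lactis) and 126 (S. pombe); for the differences from the S. cerevisiae deletion it left 215 (S. paradoxus), 289 (D00682g), 276 (M09955g), 459 (A02570), 391 (J01590), 396 (K. lactis) and 212 (S. pombe). With each library left out in turn, 209 counts stayed within 1.5 times and 7 did not: the HA strain ran from 0 to 3 genes, with 1 without HA replicate A, 2 without HA replicate C and 3 without wild type replicate B. The S. paradoxus deletion at 60 against 30 min ran from 736, without deletion replicate B at 30 min, to 1149. S. pombe ran from 277 to 635, with 278 and 277 without replicates A and B of the libraries labelled deletion and 350 without wild type replicate C.

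The inter-gene correlation mattered most for the lists: with an estimated value 240 list tests lost their call and 475 stood as before. For cytosolic ribosomal proteins the adjusted p then was 0.111 (S. cerevisiae deletion), 0.137 (deletion against HA), 0.0501 (S. paradoxus log phase), 0.279 (S. paradoxus 30 min), 0.398 (effect at 30 min against log phase), 0.62 (effect at 60 min against log phase), 0.376 (wild type 60 against 30 min), 0.192 (deletion 60 against 30 min), 0.172 (effect at 60 against 30 min), 0.653 (C. glabrata D00682g), 0.151 (C. glabrata M09955g), 0.0872 (both C. glabrata strains), 0.542 (N. castellii A02570), 0.723 (N. castellii J01590), 0.243 (K. lactis) and 0.784 (S. pombe), and for the differences from S. cerevisiae 0.0878 (D00682g), 0.259 (M09955g), 0.302 (A02570), 0.249 (J01590) and 0.359 (S. pombe). For ribosome biogenesis it was 0.0753 (S. cerevisiae deletion), 0.811 (HA strain), 0.108 (deletion against HA), 0.0786 (S. paradoxus log phase), 0.0835 (S. paradoxus 30 min), 0.142 (S. paradoxus 60 min), 0.396 (effect at 30 min against log phase), 0.085 (wild type 60 against 30 min), 0.569 (deletion 60 against 30 min), 0.253 (effect at 60 against 30 min), 0.083 (N. castellii J01590), 0.173 (both N. castellii strains), 0.0813 (K. lactis) and 0.355 (S. pombe), and for the differences 0.483 (S. paradoxus), 0.392 (J01590) and 0.0894 (S. pombe).

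With fry, a rotation test, 145 list tests gained a call and 23 lost it. Calls ended at adjusted p of 0.133 (effect at 60 min against log phase), 0.181 (C. glabrata D00682g), 0.286 (N. castellii J01590) and 0.272 (S. pombe) for ribosomal proteins and 0.596 (HA strain) and 0.122 (deletion 60 against 30 min) for ribosome biogenesis. Calls were gained for differences from S. cerevisiae at 0.0409 (S. paradoxus) for ribosomal proteins and 0.0346 (M09955g) and 0.0209 (K. lactis) for ribosome biogenesis. In K. lactis 4 lists passed in the direction opposite to camera, at 0.0303 for glycolysis, 0.0314 for hexose transport, 0.00663 for TCA and glyoxylate cycles and 1.5e-04 for TORC1 regulators. The values of fry depend on the order in which groups enter the model, since its variance estimate does: another order gave other values for the lists of C. glabrata and N. castellii, while edgeR and camera values were identical.

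Ribosomal proteins between both N. castellii strains passed without the filter (0.0425) and with TMM factors computed without the ribosomal lists (0.0484); their adjusted p ran from 0.00182 to 0.378 with each library left out. With counts summed per orthogroup the difference of ribosomal proteins from S. cerevisiae passed at 1.3e-07 (S. paradoxus). Over all lists, 119 tests lost and 59 gained a call with 1 library left out. Of the 2 ribosomal lists, single libraries moved 4 more tests across 0.05: ribosomal proteins in N. castellii J01590 (2.6e-05 to 0.0524, the highest without wild type replicate A), ribosome biogenesis in the HA strain (3.6e-05 to 0.21, the highest without HA replicate C), and the differences for ribosome biogenesis in M09955g (0.0479 to 0.273, the lowest without S. cerevisiae deletion replicate A) and for ribosomal proteins in S. paradoxus (0.0319 to 0.225, the lowest without deletion replicate B).

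Of the named genes, 12 changed sign with library size alone, and 6 of these passed the threshold in at least 1 of both settings. In K. lactis TEF1 or TEF2 (KLLA0B08998g) stood at 0.213, and in the S. paradoxus deletion at 60 against 30 min RPL3 (Spar_15.263) at 0.0536. Between the N. castellii strains RPP0 (NCAS0A02020) stood at 0.0315, RPL3 (NCAS0C05510) at 0.0543, RPS3 (NCAS0G01920) at 0.0804 and TEF1 or TEF2 (NCAS0I01000) at 0.0678. AGA1 or FIG2 (Spar_3.191) in S. paradoxus at 60 min ran from 0, without deletion replicate B, to 8.05 with each library left out. Library size alone ended the call of 36 other named genes and DESeq2 that of 35; of the calls with each library left out, 6459 stood, 258 ended, 10 were gained and 1, that of AGA1 or FIG2, ended with no fold left.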

Other observations

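No test in this part was chosen after results were seen, since it reports values only. A wild type S. cerevisiae sample at 60 min is listed in the labels without a count column, so no value can be given for it.

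Ribosomal protein genes took 22.5 ± 0.199% of counts outside ribosomal RNA genes in C. glabrata wild type (mean ± SD, n = 3), 23.4 ± 0.653% without CAGL0D00682g and 21.0 ± 0.222% without CAGL0M09955g. In N. castellii the shares were 15.9 ± 0.244% in wild type, 15.96 ± 0.710% without NCAS0A02570 and 15.6 ± 0.551% without NCAS0J01590. In K. lactis they were 12.9 ± 0.485% in wild type and 8.0 ± 0.204% in the deletion, and in S. pombe 30.6 ± 3.07% in wild type and 28.7 ± 1.27% in the libraries labelled deletion.

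Ribosomal RNA genes are listed in the count tables of 3 species and took 42.3% to 44.5% of counts in the groups of C. glabrata, 36.7% to 44.9% in those of N. castellii and 27.1% in both of K. lactis.

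In the deposited array ratios, with the sign turned to deletion over wild type, SFP1 ranged from -8.33 to -6.15 in S. cerevisiae and from -6.50 to -5.88 in K. lactis. The median of mitochondrial ribosomal proteins in K. lactis was -1.38, -0.97 and -0.87 at 30, 60 and 90 min.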
